A study of Mus musculus with 12 samples.

How the data were processed

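RNA from mouse bone marrow-derived macrophages was measured by sequencing with an mRNA library kit. The cells carried a control short hairpin (shCTRL) or a hairpin against MOF (shMOF), the acetyltransferase that the gene Kat8 encodes, and were left unstimulated or treated with lipopolysaccharide (LPS) at 100 ng/ml for 3 h. The 12 libraries form 4 groups of 3, as the sample labels give them. Per the labels' protocol, RNA was extracted from all samples at the same time and the libraries were stranded and paired-end with reads of 100 bp. The aligner, the read counter, the annotation release and whether counting used strand are not given in the sources used here. The submitters' processing notes name DESeq2, with no version, and the mm10 build.

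Each of 2 tables holds 1 knockdown comparison, shMOF against shCTRL, for 14264 genes, and neither gives values per library. Per the file headers, the authors deposited a mean normalized count per gene, a signal whose set of libraries is not stated, and this mean was identical in both tables for every gene. The authors' effect size is a log2 fold change with its standard error (SE), per the file headers. The deposited Wald statistic is a score that was found to equal the fold change over its SE, to within 1.53e-13. Each deposited p-value equalled the two-sided normal p of that statistic to within 2.83e-15, and the authors' adjusted p equalled a Benjamini-Hochberg adjustment over the genes that have one to within 1.39e-15. The authors left no adjusted p for 277 genes of the LPS table, all with a mean normalized count of at most 5.57, and these stayed without one. The smallest mean normalized count in the tables was 4.33. Library totals are unknown here, so the precision of a fold change is known through its SE only, with a median of 0.0862 unstimulated and 0.0852 at LPS 3 h over genes with a mean normalized count of at least 10.

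As the tables hold no values per library, the authors' fold changes, SE and adjusted p were used as they stand, with a threshold of 0.05 and no minimum fold. The difference of the knockdown effect between LPS 3 h and unstimulated cells was the difference of the 2 log2 fold changes over the root of the summed squared SE, with a two-sided normal p and Benjamini-Hochberg adjustment over the 12994 genes with a mean normalized count of at least 10. This takes the errors of the 2 effects as uncorrelated. No test of LPS against no LPS was made, since the deposited comparisons lie within each LPS state. Agreement between comparisons was described across genes by Pearson's r, Spearman's rho and the number of shared calls beside the product of the 2 call counts over the genes tested. Genes are not independent replicates.

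For gene lists, cameraPR of limma 3.58.1 (R 4.3.3) was run on the Wald statistic, or on the standardized difference, against all genes with a mean normalized count of at least 10, with a preset inter-gene correlation of 0.01. Without values per library the correlation could not be estimated, and 0.05 was the alternative. Adjustment was over 72 tests for the knockdown comparisons and 36 for the difference. The 41 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with fewer than 5 measured genes were counted and not tested. Of 832 list entries, 768 were found by gene name, 4 of them under another name of the same gene in GENCODE M21 or RefSeq, and the others were not analysed here. A count "adjusted over the list alone" takes the deposited p-values, or those of the difference, of the list's measured genes and adjusts over those.

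Named genes are Kat8 and Prdx1, then per comparison the 8 largest rises and 8 largest falls past the threshold with a mean normalized count of at least 50 and no clone or predicted-gene name, and up to 4 members with the smallest p of each list that is discussed. Some genes that this rule takes are not reported here. For the difference, the 6 largest in each direction under the same limits were taken. Coordinates are from GENCODE M21, on GRCm38, which is mm10, matched by Ensembl gene ID without its version for 14214 of the 14264 genes.

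Alternatives were fold changes centred on their median, adjustment over every gene or over genes with a mean normalized count of at least 10 or 50, a threshold of 0.01, a minimum log2 change of 1, a null of a change of at most 0.25, an empirical null and leaving out Kat8. For lists they were ranks, fold changes in place of the Wald statistic, a background of at least 50 and 10000 random lists of matched expression. The code was tested on simulated data, drawn with the real SE for the difference and as independent standard normal statistics for the list test. For the difference between LPS 3 h and unstimulated cells, tested over 12994 genes, 50.0% of genes given a true difference of 0.5 and 73.0% of those given 1 were recovered, with 5 calls among unchanged genes in a total of 128. The list test, run on the same number of genes, called the 1 shifted list and 0 of the 35 unshifted lists. As the simulated genes were independent, this says nothing of false calls where genes are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.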

Results

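The series measured gene expression in bone marrow-derived macrophages, cells grown from mouse marrow that respond to the bacterial product LPS through the receptor TLR4. A control hairpin (shCTRL) was compared with a hairpin against MOF (shMOF), a lysine acetyltransferase, in unstimulated cells and after 3 h of LPS at 100 ng/ml, with 3 libraries in each of the 4 groups. The comparisons ask which transcripts depend on MOF in resting and in LPS-treated macrophages, and the series title names the peroxidase PRDX1 as the protein of interest. Mean normalized counts per gene ranged from 4.33 to 855736 with a median of 446.3, and depth per library is unknown. The labels number the libraries and do not say that they came from separate animals or cultures, so p-values of single genes measure only the spread between these samples. List p-values set the genes of a list against other genes, at a preset correlation, and do not measure that spread. The labels name no other hairpin against MOF and no rescue, so other effects of the hairpin cannot be told apart from loss of MOF.

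The targeted gene was lower with the hairpin in both states. Kat8 (ENSMUSG00000030801.10) lies on chromosome 7 from 127912516 to 127925837 of GRCm38, on the plus strand. It had a log2 fold change of -2.25 (SE 0.10, adjusted p = 2.08e-101) in unstimulated cells and of -2.31 (SE 0.13, adjusted p = 4.86e-67) at LPS 3 h in the authors' deposited table, or 0.210-fold and 0.201-fold of the control level. These effects did not differ detectably between states, with a difference of -0.06 (SE 0.17, adjusted p = 0.818). Its end overlaps that of Prss8, on the opposite strand, from 127925716 to 127925837. Prdx1 (ENSMUSG00000028691.12) lies on chromosome 4 from 116685544 to 116700822, on the plus strand. It fell slightly in unstimulated knockdown cells, with a log2 fold change of -0.19 (SE 0.08, adjusted p = 0.0450) in the authors' deposited table, and had -0.07 (SE 0.07, adjusted p = 0.425) at LPS 3 h. The difference for Prdx1, 0.11 (SE 0.10), did not pass (adjusted p = 0.443). The unstimulated call for Prdx1 was lost at a threshold of 0.01 and under the empirical null.

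In unstimulated macrophages, MOF knockdown lowered cell cycle genes by the widest margin of any list and raised macrophage identity and cholesterol synthesis genes modestly. Of 40 proliferation genes measured, 39 fell and 0 rose (40 fell adjusted over the list alone), with a median log2 fold change of -1.84. Macrophage identity genes went the other way, 19 of 25 rising and 1 falling, with a median of 0.32. Of the 14264 genes tested, 3037 rose and 2538 fell at an adjusted p of 0.05. Most changes were small: 118 of the risen and 366 of the fallen genes changed by at least 2-fold.

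The 8 largest falls named by the rule were in genes of mitosis. Cdc25c, a phosphatase of mitotic entry, had a log2 fold change of -3.00 (SE 0.24, adjusted p = 4.39e-34) in the authors' deposited table. Next in the authors' deposited table were the kinase gene Pbk at -2.56 (SE 0.13) and Prc1, which bundles microtubules in cytokinesis, at -2.56 (SE 0.08). Plk1, Aspm, Hmmr, Casc5 and Kif15, all genes of the spindle or kinetochore, lay between -2.51 and -2.45 in the authors' deposited table. Within the proliferation list, Nusap1 at -2.37 (SE 0.08), Mki67 at -2.21 (SE 0.07), Kif20a at -2.20 (SE 0.08) and Ube2c at -2.28 (SE 0.09) had the smallest p in the authors' deposited table. The list test gave an adjusted p = 1.38e-110. DNA damage and repair genes fell as well, 14 of 20 lower and 1 higher (16 and 1 adjusted over the list alone, list adjusted p = 2.65e-08). Their median was -0.31, against -1.84 for the proliferation list. The repair genes were led by Fancd2 at -2.13 (SE 0.12) and Brca1 at -1.67 (SE 0.11) in the authors' deposited table. Of 5 measured haematopoietic progenitor markers 3 fell and 1 rose, the same adjusted over the list alone. In the authors' deposited table Kit had -1.81 (SE 0.38), Cd34 -0.93 (SE 0.25), Ly6a -0.70 (SE 0.17) and Cd48 0.25 (SE 0.06). The progenitor list did not pass (adjusted p = 0.695), but was called lower with fold changes in place of the Wald statistic (adjusted p = 0.0262).

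The largest rises included receptors and secreted proteins. Gpr18, a G protein-coupled receptor, rose by 2.36 (SE 0.39, adjusted p = 1.48e-08) in the authors' deposited table. In the authors' deposited table Penk, which encodes the enkephalin precursor, rose by 1.91 (SE 0.20), the formyl peptide receptor gene Fpr1 by 1.86 (SE 0.26) and haptoglobin (Hp) by 1.84 (SE 0.46). The receptor gene Hcar2 rose by 1.83 (SE 0.25), the peroxisomal transporter gene Abcd2 by 1.68 (SE 0.14), Gdpd2 by 1.99 (SE 0.47) and Serpina3f by 2.10 (SE 0.88, adjusted p = 0.0449) in the authors' deposited table. Macrophage identity genes had 20 higher and 1 lower adjusted over the list alone, with a list adjusted p = 1.81e-04. Among them the phagocytic receptor gene Mertk rose by 0.70 (SE 0.10), Itgam by 0.60 (SE 0.07), the lipid receptor gene Trem2 by 0.36 (SE 0.04) and cathepsin B (Ctsb) by 0.32 (SE 0.04) in the authors' deposited table.

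Interferon-stimulated genes rose in 21 of 37 cases and fell in 0 (23 and 0 adjusted over the list alone). The list adjusted p = 0.00651 became adjusted p = 0.114 with a correlation of 0.05. Examples from the authors' deposited table are Zbp1 at 0.81 (SE 0.16), Oasl2 at 0.61 (SE 0.10), Isg15 at 0.51 (SE 0.10) and Bst2 at 0.50 (SE 0.09). Of 20 cholesterol synthesis genes 11 rose and 2 fell (13 and 2 adjusted over the list alone, list adjusted p = 0.00250). They included Insig1 at 0.72 (SE 0.07) and the regulator Srebf2 at 0.57 (SE 0.06) in the authors' deposited table. Lysosome and autophagy genes, 19 of 30 higher and 3 lower (21 and 3 adjusted over the list alone), had a list adjusted p = 0.00144, or 0.228 with fold changes in place of the Wald statistic. In this list Neu1 rose by 0.59 (SE 0.03), and Ctsl had -0.79 (SE 0.06) in the authors' deposited table. Inflammasome genes rose in 8 of 13 cases and fell in 0 (9 and 0 adjusted over the list alone, list adjusted p = 0.0173, or adjusted p = 0.0890 with a correlation of 0.05). With fold changes in place of the Wald statistic that list had an adjusted p = 0.110. They were led by Nlrp3 at 0.67 (SE 0.06) in the authors' deposited table.

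Cytokine and chemokine genes of the primary LPS response had no call as a list in unstimulated cells (adjusted p = 0.786). Of 27 genes 3 rose and 5 fell, the same adjusted over the list alone. Members went both ways, Ccl7 falling with -1.82 (SE 0.17) and Ccl2 with -1.09 (SE 0.15) while Ccl3 rose by 0.63 (SE 0.07) in the authors' deposited table. With fold changes in place of the Wald statistic the same list was lower at adjusted p = 0.00173. The split of calls also depends on the null used, since 54.5% of calls were rises in the authors' deposited table, 47.3% after centring and 28.2% under an empirical null, which made 783 calls.

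At LPS 3 h, knockdown cells had higher levels of LPS response genes and still lower levels of most cell cycle genes. Of 27 cytokine and chemokine genes 17 rose and 3 fell (17 and 4 adjusted over the list alone), with a median log2 fold change of 0.57. In addition 18 of 19 NF-kB pathway and feedback genes rose while 1 fell (18 and 1 adjusted over the list alone), with a median of 0.54. Proliferation genes fell in 34 of 40 cases and rose in 2, Mki67 and E2f8 (34 and 2 adjusted over the list alone), with a median of -1.12. In all, 3924 of 13987 genes tested rose and 2794 fell, 306 and 387 of them by at least 2-fold.

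The cytokine Tnf rose by 1.10 (SE 0.06, adjusted p = 5.52e-77) in the authors' deposited table, with Ccl3 at 1.15 (SE 0.06), Ccl4 at 1.30 (SE 0.09) and Csf1 at 0.78 (SE 0.05), and the list adjusted p was 3.36e-04. Il27, which encodes a cytokine subunit, rose by 1.88 (SE 0.14) in the authors' deposited table. The NF-kB list had an adjusted p = 7.45e-20, and inhibitors and feedback regulators rose together with a subunit of the factor itself. Examples are Nfkbiz at 1.24 (SE 0.07), Tnfaip3 at 1.001 (SE 0.05), Nfkbia at 0.56 (SE 0.03) and Rel at 0.97 (SE 0.05) in the authors' deposited table. ERK target and immediate-early genes rose in 17 of 30 cases and fell in 4 (the same adjusted over the list alone). They were led by the phosphatase gene Dusp2 at 1.60 (SE 0.07), Maff at 0.97 (SE 0.08), Jund at 0.68 (SE 0.06) and Klf6 at 0.56 (SE 0.05) in the authors' deposited table. Their list adjusted p = 0.0173 became adjusted p = 0.157 with a correlation of 0.05, and 0.0541 with a minimum mean of 50. The receptor gene Tlr4 fell, with -0.88 (SE 0.06) in the authors' deposited table, while Ly96, its partner in LPS binding, rose by 0.69 (SE 0.07) and the adaptor gene Tab2 by 0.76 (SE 0.05). The TLR4 signalling list, 12 of 20 higher and 2 lower (the same adjusted over the list alone), did not pass (adjusted p = 0.2504).

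**Figure D1:**
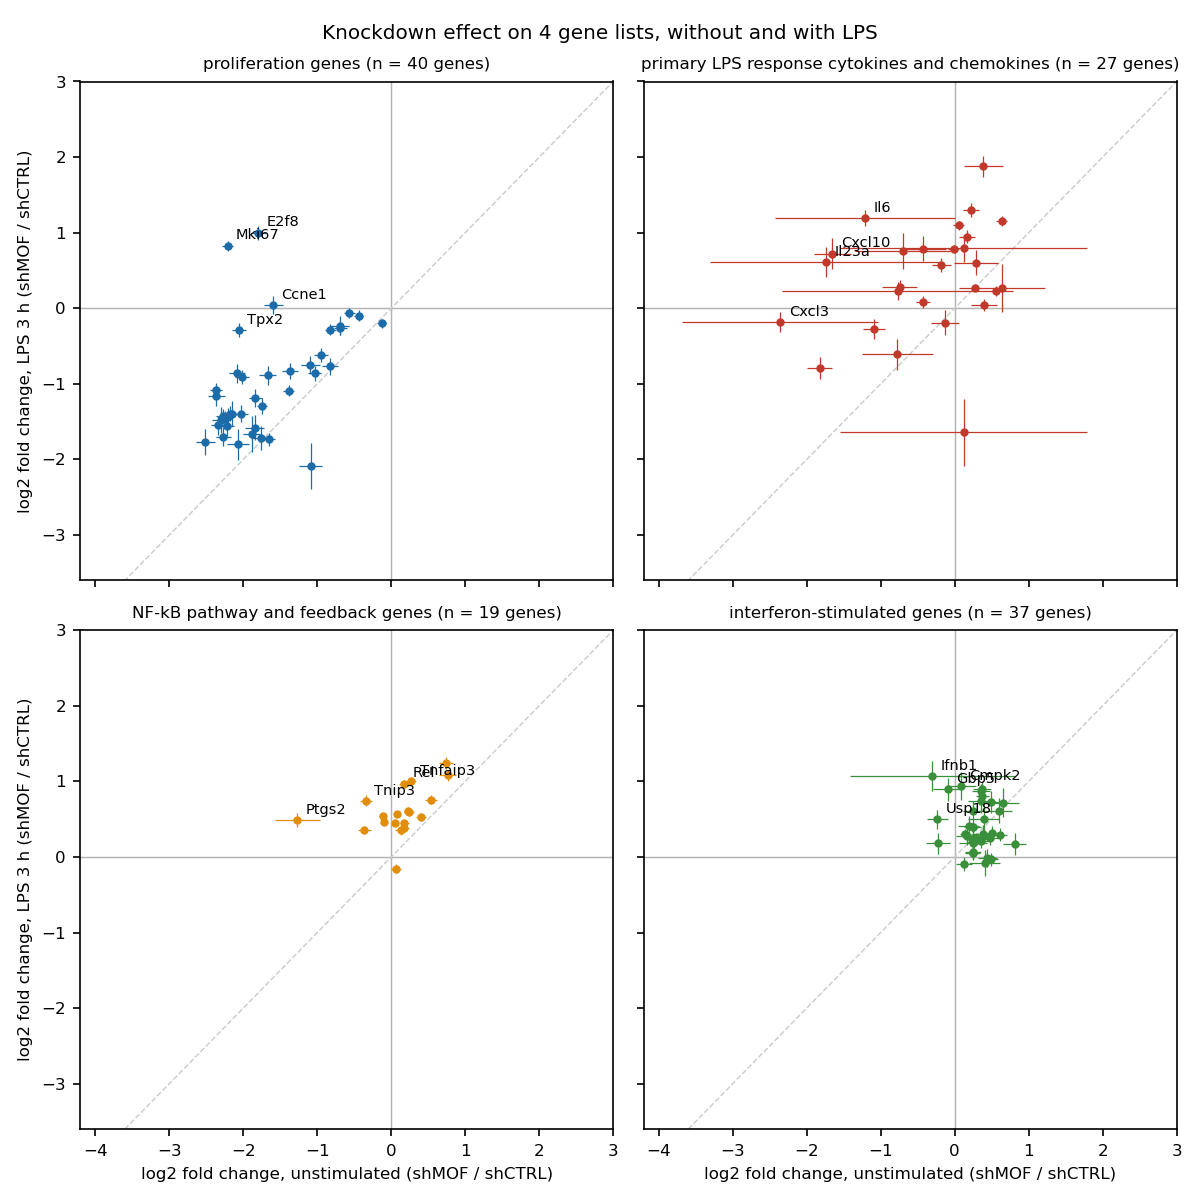
Log2 fold change of shMOF over shCTRL in unstimulated cells (horizontal axis) against that at LPS 3 h (vertical axis) for the measured genes of 4 lists, 1 point per gene, with bars of 1 SE from the authors' deposited table and a dashed line of equality. Most cytokine and NF-kB genes lie above the line, and in the proliferation panel Mki67 and E2f8 stand apart in the upper left, at 0.83 and 0.9996 on the vertical axis.

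Interferon-stimulated genes rose in 24 of 37 cases and fell in 0 (27 and 0 adjusted over the list alone, list adjusted p = 0.0114, or adjusted p = 0.148 with a correlation of 0.05). Examples are Ifi205 at 0.90 (SE 0.09), Gbp5 at 0.90 (SE 0.15), Mx2 at 0.88 (SE 0.10) and the RNA sensor gene Ifih1 at 0.80 (SE 0.08) in the authors' deposited table. Inflammasome genes rose in 9 of 13 cases and fell in 0 (the same adjusted over the list alone, list adjusted p = 0.00370, or 0.0534 with fold changes in place of the Wald statistic). They were led by Il18 at 0.89 (SE 0.09) and the DNA sensor gene Aim2 at 0.77 (SE 0.07) in the authors' deposited table. Cholesterol synthesis genes had 13 of 20 higher and 1 lower (the same adjusted over the list alone, list adjusted p = 6.75e-05). Among them were Insig1 at 1.08 (SE 0.06) and Hmgcs1 at 0.95 (SE 0.05) in the authors' deposited table. Ribosomal protein genes rose in 36 of 43 cases and fell in 0 (37 and 0 adjusted over the list alone), by little, with a median of 0.22. That median stood at percentile 68.6 of random lists of matched expression, so genes of like level rose to a similar degree. Rpl10 and Rps14 both stood at 0.35 (SE 0.05) in the authors' deposited table, and the list adjusted p = 0.00201 became adjusted p = 0.0789 with a correlation of 0.05.

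Macrophage identity genes rose in 18 of 25 cases and fell in 1 (18 and 2 adjusted over the list alone, list adjusted p = 0.0114, or adjusted p = 0.114 with a correlation of 0.05). Examples are Trem2 at 0.54 (SE 0.04) and Spi1, which encodes the lineage factor PU.1, at 0.41 (SE 0.05) in the authors' deposited table. Lysosome genes had 16 of 30 higher and 5 lower (the same adjusted over the list alone, list adjusted p = 0.0318). Their median, 0.15, stood at percentile 57.4 of random lists of matched expression. Matrix and integrin genes had 16 of 25 higher and 1 lower (the same adjusted over the list alone, list adjusted p = 0.0427). Both calls were lost, at adjusted p = 0.205 for each, with a correlation of 0.05. With fold changes in place of the Wald statistic the calls of the lysosome (adjusted p = 0.442), matrix (0.0908), macrophage identity (0.117) and ribosomal protein genes (0.0728) were lost. A minimum mean of 50 also ended the calls of the lysosome (adjusted p = 0.0692) and matrix genes (0.0863). DNA damage and repair genes fell in 10 of 20 cases and rose in 0 (the same adjusted over the list alone, list adjusted p = 0.00576, or adjusted p = 0.0646 with a correlation of 0.05). Their median was -0.25. Among them Brca1 was at -2.11 (SE 0.15) in the authors' deposited table. The proliferation list, with an adjusted p = 7.27e-21, was led by Cdk1 at -1.73 (SE 0.09), Ube2c at -1.43 (SE 0.09), Top2a at -1.39 (SE 0.09) and Rrm1 at -1.09 (SE 0.07) in the authors' deposited table.

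The largest fall at LPS 3 h was in Fads1, a fatty acid desaturase gene, at -3.15 (SE 0.11, adjusted p = 4.25e-184) in the authors' deposited table. Gcsh, of the glycine cleavage system, followed at -2.58 (SE 0.12), the replication gene Ticrr at -2.51 (SE 0.29), the cannabinoid receptor gene Cnr2 at -2.50 (SE 0.45) and the Polycomb gene Cbx6 at -2.36 (SE 0.19) in the authors' deposited table. The mitotic kinesin genes Kif18a at -2.39 (SE 0.41) and Kif14 at -2.37 (SE 0.33) and the cohesin acetyltransferase gene Esco2 at -2.33 (SE 0.41) completed the group in the authors' deposited table. The largest rises there were Tmem200b at 2.50 (SE 0.18), the organic anion transporter gene Slco2b1 at 2.11 (SE 0.20), Gprc5c at 2.04 (SE 0.25) and Lyzl4 at 1.92 (SE 0.19) in the authors' deposited table. Tnfsf9, a co-stimulatory ligand of the TNF family, rose by 1.88 (SE 0.04), Arap2 by 1.87 (SE 0.11) and the Ras activator gene Rasgrp3 by 1.79 (SE 0.11) in the authors' deposited table.

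**Figure D2:**
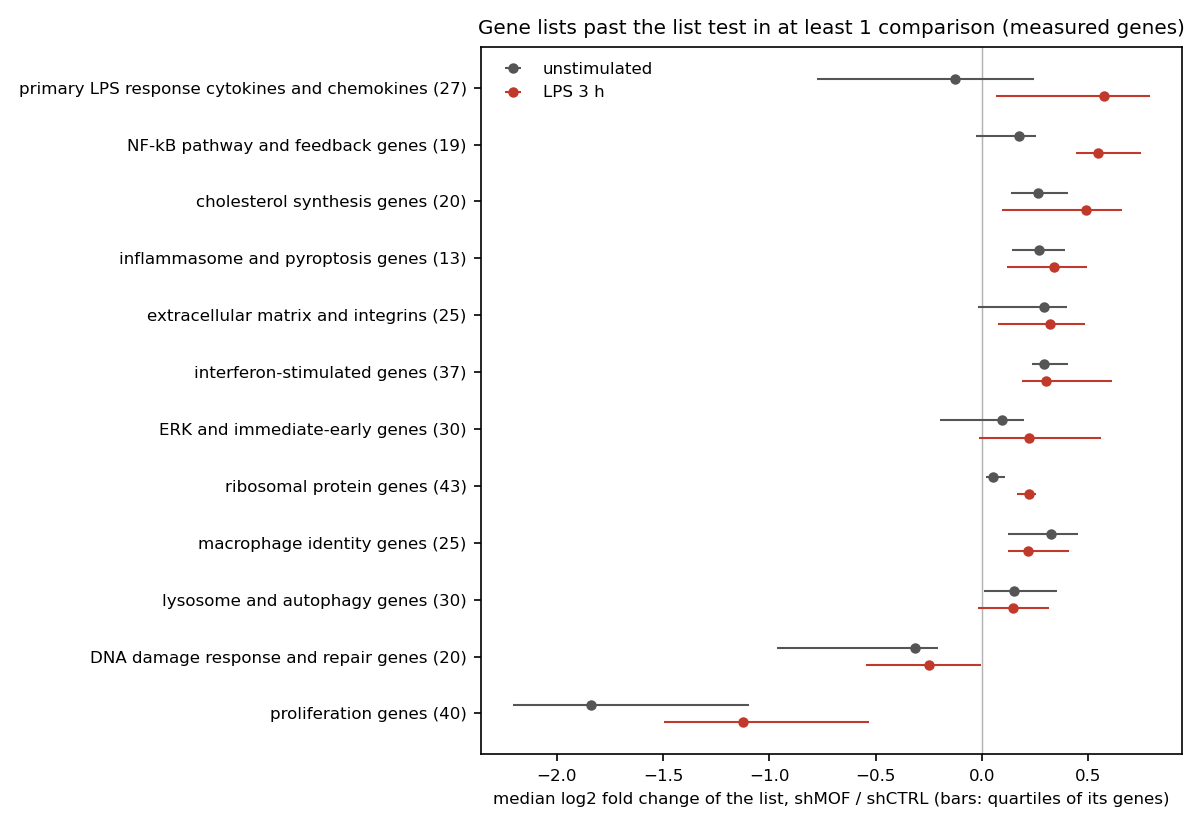
Median log2 fold change of shMOF over shCTRL (horizontal axis) of the 12 gene lists that passed the list test in at least 1 comparison, with the number of measured genes in brackets; grey is unstimulated, red is LPS 3 h and bars span the quartiles of the genes of a list. The proliferation list lies at -1.84 and -1.12, and the cytokine list moves from -0.13 to 0.57.

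Lists chosen for the redox and metabolic side of MOF and PRDX1 did not pass in either state with the Wald statistic. The list test asks whether members move in 1 direction, so it can miss a list whose members move both ways. Of all genes tested, 39.1% were called unstimulated and 48.0% at LPS 3 h. Of 15 peroxiredoxin and thioredoxin genes 6 rose and 7 fell in unstimulated cells (the same adjusted over the list alone, list adjusted p = 0.786). Their median was 0.05, while the mean and the test pointed lower. Only 2 of these 15 genes were not called in unstimulated cells. At LPS 3 h 4 rose and 5 fell (the same adjusted over the list alone, list adjusted p = 0.342). Prdx6 fell by the widest margin among them in both states, at -1.10 (SE 0.05) and -0.96 (SE 0.05) in the authors' deposited table. Txnrd1, thioredoxin reductase, had -0.47 (SE 0.06) unstimulated and 0.29 (SE 0.05) at LPS 3 h in the authors' deposited table. The thioredoxin inhibitor gene Txnip had 0.35 (SE 0.05) and -0.28 (SE 0.05), all past the threshold in the authors' deposited table. NRF2 targets and antioxidant enzymes had 3 of 24 higher and 8 lower unstimulated (list adjusted p = 0.305), and 5 higher and 6 lower at LPS 3 h (list adjusted p = 0.448). All 4 counts were the same adjusted over the list alone, and heme oxygenase (Hmox1) had -0.66 (SE 0.10) at LPS 3 h in the authors' deposited table. Nuclear-encoded oxidative phosphorylation genes changed in few of 70 cases, 4 rising and 14 falling unstimulated (4 and 12 adjusted over the list alone, list adjusted p = 0.448). At LPS 3 h 6 were higher and 12 lower (5 and 11 adjusted over the list alone, list adjusted p = 0.127). Cox6c was the lowest in p in both states, at -0.77 (SE 0.06) and -0.68 (SE 0.05) in the authors' deposited table. Glycolysis genes had 4 of 22 higher and 4 lower unstimulated (the same adjusted over the list alone, list adjusted p = 0.760). Their median was -0.02, while the mean and the test pointed higher. At LPS 3 h 4 were higher and 8 lower (5 and 8 adjusted over the list alone, list adjusted p = 0.614), with the phosphofructokinase gene Pfkp at 0.82 (SE 0.05) at LPS 3 h in the authors' deposited table. Against random lists of matched expression some of these medians were low, though small. The NRF2 list, with medians of -0.10 unstimulated and -0.06 at LPS 3 h, stood at percentiles 0.33 and 0.12. The glycolysis list stood at 0.60 and the oxidative phosphorylation list at 2.41 at LPS 3 h, and for the difference the glycolysis list stood at 0.93. Mitochondrially encoded genes had 1 of 15 higher and 0 lower unstimulated, and 8 and 0 at LPS 3 h (list adjusted p = 0.990 and 0.737). NADPH oxidase and nitric oxide synthase genes had 4 of 7 and 0, then 4 and 2 (list adjusted p = 0.0878 and 0.579). Itaconate and tricarboxylic acid cycle genes had 11 of 26 and 5, then 13 and 4 (list adjusted p = 0.343 and 0.126).

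The knockdown effect itself differed between the states in 3977 of 12994 genes, with 2363 more positive and 1614 more negative under LPS. Under the empirical null 270 and 65 genes passed in these directions. The median difference was 0.80 for cytokine and chemokine genes (13 of 27 more positive and 1 more negative, the same adjusted over the list alone, list adjusted p = 2.39e-04). It was 0.40 for NF-kB genes (14 of 19 and 0, or 17 and 1 adjusted over the list alone, list adjusted p = 1.70e-12). For proliferation genes it was 0.60 (30 of 40 and 1, the same adjusted over the list alone, list adjusted p = 4.56e-18). Ribosomal protein genes had a median difference of 0.15 (9 of 43 and 0, or 5 and 0 adjusted over the list alone, list adjusted p = 0.0350, or adjusted p = 0.377 with a correlation of 0.05). That call was also lost with fold changes (adjusted p = 0.525) and with a minimum mean of 50 (adjusted p = 0.0948). The ribosomal median difference stood at percentile 88.3 of random lists of matched expression. No other list of the 36 tested passed, the nearest being ERK and immediate-early genes with a median difference of 0.28 (16 of 30 more positive and 4 more negative, or 18 and 5 adjusted over the list alone, list adjusted p = 0.0542), whose median stood at percentile 100 of random lists of matched expression.

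Mki67, which encodes the Ki-67 antigen of dividing cells, lies on chromosome 7 from 135689784 to 135716361, on the minus strand. It went from -2.21 (SE 0.07) unstimulated to 0.83 (SE 0.06) at LPS 3 h in the authors' deposited table. The difference was 3.04 (SE 0.10, adjusted p = 7.61e-202). E2f8, an atypical E2F factor gene, lies on the same chromosome and strand from 48866429 to 48881596. It went from -1.80 (SE 0.10) to 0.9996 (SE 0.09) in the authors' deposited table. The difference was 2.80 (SE 0.14, adjusted p = 3.36e-91). Each is overlapped in part by an annotated transcript on the opposite strand, Gm45240 and Gm2788, and whether counting used strand is not given in the sources used here. The protease gene Adamts4 went from -1.41 (SE 0.45) to 1.68 (SE 0.06) in the authors' deposited table (difference 3.09, SE 0.46, adjusted p = 4.02e-10). For Tmem200b, Nos2, which encodes inducible nitric oxide synthase, and Gem the unstimulated value was imprecise and did not pass. It was -1.36 (SE 1.44), -2.21 (SE 1.12) and -1.57 (SE 0.74) in the authors' deposited table. At LPS 3 h the authors' deposited table gave 2.50 (SE 0.18), 0.97 (SE 0.11) and 1.32 (SE 0.07).

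In the negative direction, Cnr2 went from 0.03 (SE 0.08) to -2.50 (SE 0.45), Fads1 from -1.14 (SE 0.07) to -3.15 (SE 0.11) and Hp from 1.84 (SE 0.46) to -0.59 (SE 0.18) in the authors' deposited table. Gdpd2 went from 1.99 (SE 0.47) to -0.47 (SE 0.38), Cd38, an ectoenzyme gene, from 0.96 (SE 0.81) to -1.50 (SE 0.22) and Trem3 from 0.64 (SE 0.46) to -1.14 (SE 0.40) in the authors' deposited table. Their differences had adjusted p between 1.93e-52 for Fads1 and 0.0149 for Trem3.

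**Figure D3:**
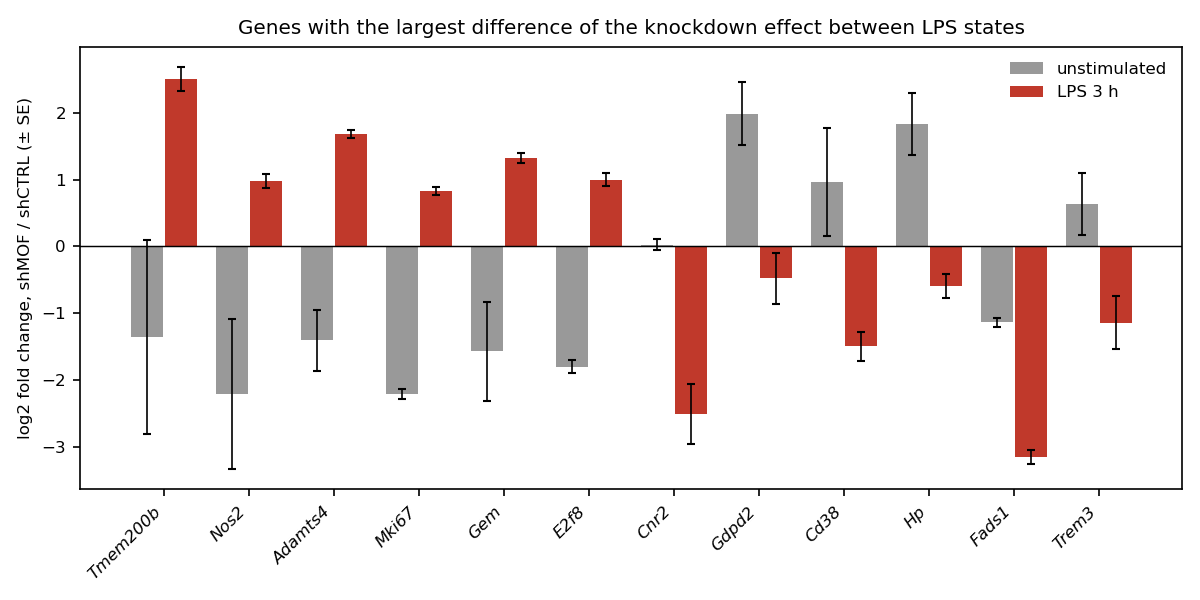
Log2 fold change of shMOF over shCTRL (vertical axis) with bars of 1 SE from the authors' deposited table, in unstimulated cells (grey) and at LPS 3 h (red), for the 6 genes with the most positive and the 6 with the most negative difference. Mki67 and E2f8 change sign with small errors, while the unstimulated bars of Tmem200b and Nos2 have SE of 1.44 and 1.12.

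Across genes the 2 comparisons resembled each other in part. Pearson's r of the log2 fold changes was 0.487 and Spearman's rho 0.426 over 12994 genes, which are not independent replicates. Of these genes 1770 rose in both states, against 896.9 for independent lists of the same sizes, and 1324 fell in both, against 536.8. Another 339 genes fell in unstimulated cells and rose at LPS 3 h, and 212 did the opposite, against 750.9 and 641.2 for independent lists. The comparisons share no library. Fits on separate sets of libraries would not give the same mean normalized count for every gene, and 0 genes differed between the comparisons. This argues against separate fits. The terms of the authors' model are not given in the sources used here.

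Of 8 lists of markers of other cell types that a marrow culture could hold, 4 had enough measured genes to test, and none of these 4 passed in either state with the Wald statistic. The stromal and endothelial list had 3 of 11 genes higher and 0 lower unstimulated (the same adjusted over the list alone, list adjusted p = 0.737). At LPS 3 h 5 were higher and 0 lower (the same adjusted over the list alone, list adjusted p = 0.448), with Col1a1 at 0.42 (SE 0.13) and 0.52 (SE 0.12) in the authors' deposited table. Of the 5 progenitor markers 1 rose and 2 fell at LPS 3 h (1 and 3 adjusted over the list alone, list adjusted p = 0.366), and with fold changes in place of the Wald statistic the list was lower at adjusted p = 0.00883. The dendritic cell list had 2 of 5 genes higher and 0 lower unstimulated (the same adjusted over the list alone, list adjusted p = 0.270) and 3 and 0 at LPS 3 h (4 and 0 adjusted over the list alone, list adjusted p = 0.420), with a median of 0.37. Of 8 monocyte markers 4 were higher and 1 lower unstimulated (4 and 2 adjusted over the list alone, list adjusted p = 0.563), and 2 were higher and 2 lower at LPS 3 h (the same adjusted over the list alone, list adjusted p = 0.558). For the difference 3 were more negative and 0 more positive (the same adjusted over the list alone, list adjusted p = 0.288). Against random lists of matched expression the stromal list stood at percentile 99.1 unstimulated and 99.7 at LPS 3 h, the progenitor list at 0.20 and 0.15, and the monocyte list at 97.9 unstimulated. The neutrophil, lymphocyte, mast cell and erythroid lists had 4, 3, 2 and 2 measured genes and were not tested.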

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

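The test of the difference was fixed before the data were examined, and so were the list tests with each of their settings. Apart from these and the tests of gene length and GC content, the tests in this part were chosen after the result was seen. The knockdown effect differed between LPS 3 h and unstimulated cells in 3977 genes by the test of the difference. The values, as the log2 fold change at LPS 3 h minus that in unstimulated cells, were 3.86 for Tmem200b, 3.18 for Nos2, 3.09 for Adamts4, 3.04 for Mki67, 2.89 for Gem and 2.80 for E2f8. In the other direction they were -2.53 for Cnr2, -2.46 for Gdpd2, -2.46 for Cd38, -2.42 for Hp, -2.02 for Fads1 and -1.78 for Trem3. At the level of lists the same test called the cytokines and chemokines (median difference 0.80), the NF-kB genes (0.40), the proliferation genes (0.60) and the ribosomal protein genes (0.15). The ribosomal call was lost with a correlation of 0.05 (adjusted p = 0.377), with fold changes in place of the Wald statistic (0.525) and with a minimum mean of 50 (0.0948). Its median difference stood at percentile 88.3 of random lists of matched expression.

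The fall of the proliferation genes in unstimulated knockdown cells had a list median of -1.84. Centring took off only the median of all genes, 0.03, and so was no test. It left -1.87 (95% bootstrap interval over the 40 genes, -2.11 to -1.66). A scaling shift would move random lists of matched expression alike, and the list median stood at percentile 0 of them. Taking off the median of genes of like length and GC content left -1.90 (-2.11 to -1.68). These values argue against a scaling shift, length and GC content as the whole cause of the fall. Fewer progenitor cells in the knockdown cultures could also lower these genes, and this cannot be told apart from less division by the macrophages, since the median of the progenitor markers was -0.70 over only 5 measured genes, with an interval from -1.81 to 0.28. An effect of MOF loss on the cell cycle stays open as a hypothesis beside it.

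The larger knockdown effect on the cytokine and NF-kB genes at LPS 3 h had a median difference of 0.61 over 46 genes. The 95% bootstrap interval over these genes was 0.38 to 0.80. Like the other bootstrap intervals in this part, it holds no spread between libraries. Random lists of like mean normalized count, which a scaling shift would move alike, had a median difference of 0.0736 (95% of them from -0.02 to 0.15). Both lists had already stood at percentile 100 of random lists of matched expression, so this was no independent test. Centring moved each difference by only -0.000742 and so was no test. The median difference was 0.64 after taking off genes of like length and GC content (0.42 to 0.76) and 0.51 after taking off genes of like mean normalized count (0.30 to 0.72). These values argue against a scaling shift, length and GC content, and the mean normalized count as the whole cause. That mean is a single value per gene for both states, so matching on it does not match the level in unstimulated cells. Low levels of these genes in unstimulated cells therefore stay open as a source of the difference. A stronger response of these genes to LPS in cells with less MOF is a hypothesis, found and tested on the same data, and a difference in cell state between cultures was not tested.

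The SE of abundant genes were larger in the unstimulated comparison. Over the 91 genes with a mean normalized count of at least 30000, the squared quotient of the SE, unstimulated over LPS 3 h, had a median of 1.23 and quartiles of 1.23 and 1.24. A model of 4 equal groups and no further term gives 1 for such genes, below the lower quartile of 1.227. A model with 1 library fewer in an unstimulated arm gives a value above the upper quartile. A further term in the authors' model, or weights on libraries, stays open and was not tested. Such a term could correlate the errors of the 2 effects: with a correlation of 0.25 in place of 0 the difference passed in 4892 genes, and with -0.25 in 3265.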

How the results depend on the processing

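Counts of calls depended on how small a change was counted, and so did the balance of rises and falls. No named gene or list that was called turned to a call in the other direction under the alternatives tried. Centring left 2577 rises and 2875 falls unstimulated, against 3037 and 2538. With a minimum log2 change of 1 there were 484 calls unstimulated (118 higher, 366 lower) and 693 at LPS 3 h (306 and 387), as fewer genes meet the added limit, and falls then outnumbered rises in both states. Against a null of a change of at most 0.25 there were 1492 (595 and 897) and 2447 (1426 and 1021). The empirical null, which widens the reference spread to that of all genes, left 783 (221 and 562), 674 (453 and 221) and, for the difference between states, 335 (270 more positive, 65 more negative). At a threshold of 0.01 the more negative differences numbered 1023. Every other count of genes under centring, the filters and leaving out Kat8 stayed within 1.5 times. With a correlation of 0.05, 10 of the 19 list calls of the knockdown comparisons held. They were proliferation and cholesterol synthesis in both states, DNA repair, macrophage identity and lysosome unstimulated, and cytokines, NF-kB and inflammasome at LPS 3 h. For the difference 3 of 4 list calls held. Fold changes in place of the Wald statistic ended the calls of the inflammasome and lysosome genes in both states and of the ribosomal and matrix genes at LPS 3 h, and that of the ribosomal genes for the difference. Lost calls with a correlation of 0.05 included the interferon-stimulated genes (adjusted p = 0.114 unstimulated and 0.148 at LPS 3 h) and the macrophage identity genes at LPS 3 h (0.114), which were also lost with fold changes in place of the Wald statistic (0.117) and whose median stood at percentile 63.8 of random lists of matched expression. For the difference that list's median stood at percentile 2.26. The unstimulated cytokine list was called lower with fold changes (adjusted p = 0.00173) and its median stood at percentile 0.06. By ranks the scavenger receptor genes (adjusted p = 0.0236 and 0.0132) and, unstimulated, the antigen presentation (0.0349) and matrix genes (0.0493) were called higher. For the difference the median of the repair genes stood at percentile 99.96 and that of the antigen presentation genes at 0.81. The causes were not tested. The error correlations of 0.25 and -0.25 were chosen after seeing the data. No paired analysis was possible because the tables give no values per library, and for the same reason leaving out each replicate, other splits of the samples and the alternatives planned for count tables or normalized values could not be run, nor could the effect of LPS. Depth per library is unknown. The simulated recovery of a difference of 1 was 73.0%, and whether low counts account for the genes missed was not tested.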

Other observations

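Among genes of lipid handling and stress that the account above leaves out, several moved in knockdown cells. The stress gene Herpud1 rose in both states, by 1.13 (SE 0.11) and 1.31 (SE 0.10) in the authors' deposited table, while the amino acid transporter gene Slc3a2 fell, at -0.59 (SE 0.05) and -0.72 (SE 0.04). Phgdh, the first enzyme of serine synthesis, fell in unstimulated cells with -1.69 (SE 0.18) and had -0.10 (SE 0.12) at LPS 3 h in the authors' deposited table, a difference of 1.59 (SE 0.22, adjusted p = 1.03e-11). Apoe rose by 0.87 (SE 0.14) and 0.91 (SE 0.12), and the alternative activation markers Clec10a by 0.94 (SE 0.10) and 1.43 (SE 0.11) and Mrc1 by 0.34 (SE 0.09) and 0.98 (SE 0.08) in the authors' deposited table. The unfolded protein, LXR and alternative activation lists that hold them did not pass with the Wald statistic, but other settings called each of them. Alternative activation was higher at LPS 3 h with a minimum mean of 50 (adjusted p = 0.0288), LXR was higher unstimulated by ranks (0.0493), and the unfolded protein list was more positive for the difference with fold changes (0.04999). Of 10 alternative activation genes measured, 3 were higher and 2 lower unstimulated, and 5 higher and 2 lower at LPS 3 h (the same adjusted over the list alone). Among acetylation enzymes, Sirt1 had -0.48 (SE 0.07) unstimulated and 0.49 (SE 0.06) at LPS 3 h in the authors' deposited table, both past the threshold, with a difference of 0.97 (SE 0.10, adjusted p = 5.60e-22).

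Genes that fell in unstimulated cells and rose at LPS 3 h, with a mean normalized count of at least 50 and past the test of the difference, numbered 325, and the opposite class 205. The examples here were chosen after their values were seen. The interferon-induced chemokine gene Cxcl10 went from -1.65 (SE 0.25) to 0.72 (SE 0.21), Slfn9 from -1.19 (SE 0.15) to 0.87 (SE 0.14) and Ptgs2, the inducible cyclooxygenase gene, from -1.27 (SE 0.30) to 0.49 (SE 0.09) in the authors' deposited table. In the other class the phosphatase gene Dusp6 went from 0.43 (SE 0.08) to -0.80 (SE 0.17) and the transcription factor gene Foxo3 from 0.49 (SE 0.08) to -0.67 (SE 0.10) in the authors' deposited table.

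The tests in this paragraph were chosen after the result was seen. The estimate used here was reworked several times while the data were examined, and a first simulation, whose noise was set by hand, was replaced after its result was seen. The tables hold no comparison of LPS with no LPS, but for counts the SE grows as the mean falls, so the 2 SE of a gene, its 2 fold changes and its overall mean allow a rough estimate of its change with LPS in control cells, centred on the median gene. The squared unstimulated SE was first divided by the squared SE quotient of the most abundant genes, whose cause is unknown. Whether that correction holds at low counts was not tested. The estimate put 26 of 27 cytokine and chemokine genes, 18 of 19 NF-kB genes, 32 of 37 interferon-stimulated genes and 0 of 43 ribosomal protein genes among those that rise by more than 1 on the log2 scale. Among 40 proliferation genes 22 were estimated to fall and 0 to rise. Of 1116 genes estimated to rise, 61.6% were higher and 6.27% lower in knockdown cells at LPS 3 h, against 27.0% and 10.8% unstimulated. Of 871 estimated to fall, 7.69% were higher and 48.7% lower at LPS 3 h, against 21.1% and 31.7% unstimulated. The estimate rests on the SE, so genes estimated to rise tend to have a larger SE unstimulated. Fewer of them can pass there whatever the effect. Median log2 fold changes went from 0.12 unstimulated to 0.43 at LPS 3 h in genes estimated to rise. In those estimated to fall they went from -0.07 to -0.48. The median difference of the knockdown effect was higher by 0.553 in the first class than in the second (95% bootstrap interval 0.470 to 0.613), and by 0.572 without genes of any fixed list. The bootstrap intervals in this paragraph resample genes, which are not independent replicates, and hold no spread between libraries. A candidate explanation is that many genes that respond to LPS respond further when MOF is low, which does not hold for every group. The 22 proliferation genes estimated to fall had a median difference of 0.75 (95% bootstrap interval 0.46 to 0.78), which argues against a further fall with LPS in that group. The 32 interferon-stimulated genes estimated to rise had 0.11 (-0.06 to 0.24), which leaves a further rise open. Coupling between the estimate and the fold changes could also give a gap, and 20 data sets simulated with no such relation gave a median of -0.070, from -0.102 to -0.009, which as a simulated bound leaves it open.

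MOF is known from flies as the enzyme that acetylates histone H4 on the male X chromosome, so lower X-linked expression was tested as a hypothesis, with the bound set before the result was seen. The median of 428 X-linked genes minus that of 12500 autosomal genes was -0.024 (95% bootstrap interval -0.069 to 0.013) unstimulated and 0.034 (-0.009 to 0.076) at LPS 3 h. Both intervals lie above -0.1, the size set for a fall, so a fall of X-linked genes as a class by that much was not seen. The intervals resample genes, which are not independent replicates, and hold no spread between libraries.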
